A study of Mus musculus with 2 samples.

How the data were processed

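The series holds 2 samples from kidneys of B6 mice with aristolochic acid nephropathy, a chronic kidney disease caused by plant toxins, at week 2 per the labels. One is a single-cell RNA-seq sample of sorted CD45-positive cells, CD45 being the surface protein shared by nearly all leukocytes, and the other is a Visium section, a slide on which RNA is captured in spots of known position. Per the labels' protocols, kidney sections were digested with Liberase, a collagenase mixture, and viable CD45-positive cells were collected by flow cytometry for the 3' Chromium chemistry, in which each captured RNA molecule carries a unique molecular identifier (UMI). The organism label, the reference and every gene identifier are mouse, while the protocol text speaks of human kidneys and the cell type label of mesenchymal stem cells. Those words were not used. The title of the single-cell sample also names week 1, and it names a single mouse, whereas its time label, the series title and the deposited run settings name week 2.

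The deposited values are raw counts of UMIs per gene and cell, with no normalization, written by Cell Ranger 6.1.1 per the file headers. The submitters' processing notes name Cell Ranger 6.0, Seurat 4.3.0 and the mm10 build, and the deposited run settings name an mm10 reference, 1 gene expression library, 1 hashtag library and 2 hashed samples marked by hashtags 301 and 305. A hashtag is an antibody-borne barcode that records which sample a cell came from. The matrices hold the barcodes that the authors' run had filtered and assigned to a hashtag, 3315 in hashed sample 1 and 3700 in hashed sample 2, and in all 7015 cells the highest hashtag count was that of its own sample. Because both hashed samples were captured in 1 library, they share every step after pooling. The labels do not say that they are separate animals. For the Visium section the deposited files used here give spot positions, so that its expression was not analysed here.

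Cells with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, which removed 414 barcodes. Doublets, droplets holding more than 1 cell, were then removed: 50 by Scrublet as implemented in scanpy and 6 because the top hashtag was under 10 counts or under 2 times the next, together 0.848% of the cells passing the filter. The 6545 remaining cells were scaled to 10000 UMIs, log-transformed and clustered with scanpy 1.11.5 and leidenalg 0.10.2, on 2000 variable genes, 30 principal components, 15 neighbours and resolution 1. Genes of MHC class II presentation and mitochondrial genes were left out of the clustering, so that no cluster was formed on the MHC class II level. Versions were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1 and scikit-learn 1.9.0. No deposited table of cell types was used, and clusters were called "like" a cell type only from 23 marker sets fixed before the data were examined. At least 3 markers of the set had to be detected. A detected marker had at least 50 CPM and at least 2 times the median over all clusters, with 10 CPM added to both. A cluster in which no set scored clearly stayed unnamed and is given by number. Shares of cells, names and class sizes therefore depend on rebuilt clusters.

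For each comparison of 2 cell classes, the UMIs of all cells of a class were summed per hashed sample and scaled for the total UMIs of the class to CPM, the usual unit of count data. The ratio of the classes was taken on the log2 scale with a pseudocount of 10 CPM, which understates differences of low genes. A gene was measured when it reached 50 CPM in at least 1 of the classes in each hashed sample, and was counted as higher or lower when it differed by at least 1.5-fold the same way in both. Cells are not replicates, and the labels name no replicate animals, so that no test was made and no p-value is given. Intervals are exact 95% intervals (Clopper-Pearson for shares, exact conditional for ratios of counts) and cover counting error only, not differences between animals. A count of 0 is given with the share that 3 counts of the total would make. To compare shares of cells with a UMI of a gene, each cell was thinned at random to 1000 UMIs, and shallower cells were left out.

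Named genes are the 10 with the largest and the 10 with the smallest mean log2 ratio among those counted, leaving out the genes that define the classes, mitochondrial, ribosomal, immunoglobulin, T cell receptor, sex-linked marker and unnamed gene models, and at most 4 members of each of 26 gene lists. The marker sets, the gene lists, the naming rule, the filters, the fold rule and the alternatives were fixed before the data were examined. A gene list with at least 5 measured members was also set against 10000 random lists of the same size matched on mean expression. That percentile describes these cells and is no test. Several lists share genes with the marker sets that named the clusters, which is said where it applies.

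The fold rule was tested on simulated counts drawn from the real class means and totals with a dispersion of 0.02 and 200 changed genes. With MHC II-low against MHC II-high totals (2594 genes), it recovered 8 of 50 genes changed 1.5-fold, 37 of 50 changed 2-fold, 49 of 50 changed 3-fold and 48 of 50 changed 5-fold, with 6 false calls among 2399 unchanged genes. With resident macrophage against monocyte totals (2611 genes), the recovered numbers were 9, 40, 46 and 47 of 50 at those fold sizes, with 5 false calls among 2425. With CD4 against CD8 T cell totals (2594 genes), they were 7, 33, 48 and 50 of 50, with 9 false calls among 2403. A list of counted genes is therefore far from complete under 2-fold.

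Gene positions are those of GENCODE M21, on the GRCm38 assembly that mm10 names, in which 32158 of the 32285 gene identifiers (99.6%) were found. Alternatives changed 1 choice at a time: the cell filter, doublet removal, clustering resolution, each hashed sample alone, TMM scaling factors from edgeR 4.0.16 in R 4.3.3, the pseudocount, the filter on low values, the fold, the dividing level of MHC II, thinning depth and the hashtag minimum. EdgeR served for those factors alone.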

Results

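CD45-positive cells of the diseased kidney were profiled to describe MHC II-negative resident macrophages and CD4 T cells, the populations named in the design of the series. No untreated kidney was among the samples used here, so that cell classes were compared with each other within the same kidneys. After filtering, 3083 cells of hashed sample 1 and 3462 cells of hashed sample 2 remained, with medians of 5664 and 6562 UMIs and of 1887 and 2125.5 genes per cell. The deposited matrices held 20743037 and 25314154 UMIs. Paired values are given for hashed sample 1 and then hashed sample 2 throughout. The accompanying Visium section had 2116 spots over tissue, 42.4% of its spots, and its expression was not analysed here.

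Resident macrophage-like cells, which carried the complement genes C1qa, C1qb and C1qc, were the most numerous class. They made up 30.8% of cells in hashed sample 1 (95% interval 29.2 to 32.5, 951 cells) and 40.4% in hashed sample 2 (38.8 to 42.1, 1399 cells). With each hashed sample clustered alone, the shares were closer together, at 28.3% and 30.1%. T cell-like cells made up 30.4% (28.8 to 32.1) and 13.03% (11.9 to 14.2). Most of these were CD4 T cell-like, at 18.5% and 7.39% of all cells, followed by CD8 T cell-like cells, at 8.63% and 4.91%, and by a cycling cluster of mixed T cells, at 3.28% and 0.722%. Type 2 dendritic cell-like cells held 8.30% and 13.4%, monocyte-like cells 4.38% and 4.68%, NK cell-like cells 2.11% and 1.33%, type 1 dendritic cell-like cells 1.43% and 1.94%, and migratory dendritic cell-like cells 1.85% and 1.07%. The type 2 dendritic cell-like class joined clusters 5 (472 cells) and 11 (249 cells), which were not alike. Cluster 11, led by Cxcl2, Tnfsf9 and Il1b, held C1qa at 1943 and 2321 CPM, against 192.5 and 202 CPM in cluster 5. The dendritic cell marker Cd209a stood at 193 and 107 CPM in cluster 11, against 359 and 641 CPM in cluster 5. B cell-like and neutrophil-like cells were each under 1% of cells in both hashed samples.

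Some droplets of the CD45 sort carried markers of kidney cells. Proximal tubule-like cells, with Slc34a1 at 1520 and 1134 CPM, made up 2.21% and 2.08% of cells, loop of Henle or distal tubule-like cells 0.616% and 0.867%, and endothelial cell-like cells numbered 14. These droplets also held leukocyte RNA: in the proximal tubule-like class Ptprc, which encodes CD45, stood at 319.6 and 293 CPM, against 303.5 and 354 CPM in resident macrophage-like cells, and C1qa at 2067 and 2499 CPM. Another 16.4% and 19.6% of cells fell in 4 myeloid clusters that stayed unnamed. Across genes, which are not independent replicates, log2 CPM of the hashed samples correlated with Pearson r of 0.982 in resident macrophage-like cells and 0.982 in CD4 T cell-like cells, but 0.887 in NK cell-like and 0.602 in B cell-like cells, the lowest of the 11 classes compared. The differences in share have no replicate behind them. With 1 capture, the number of cells of a class also depends on digestion and on gating in the sort.

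**Figure D1:**
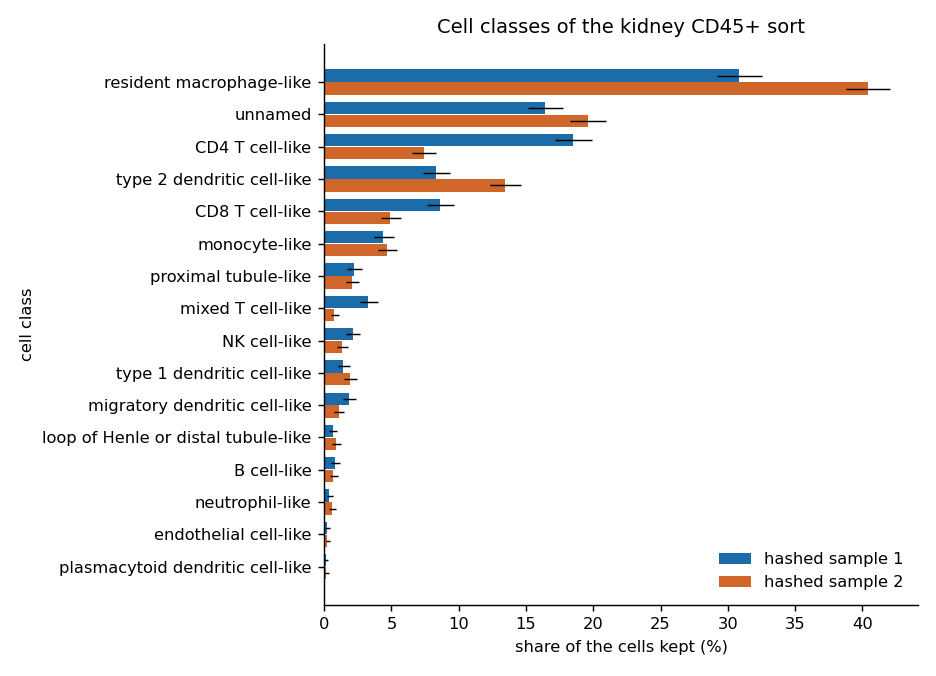
Share of the cells kept (%, horizontal axis) for each cell class (vertical axis) in hashed samples 1 and 2. Bars are shares and lines are exact 95% intervals for counting error; resident macrophage-like cells lie at 30.8% and 40.4%, and CD4 T cell-like cells at 18.5% and 7.39%.

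Resident macrophage-like cells spanned low and high levels of the MHC class II genes, which encode the proteins that present peptides to CD4 T cells. The level of H2-Aa, H2-Ab1 and H2-Eb1 together had 3 modes, at 7.32, 20.1 and 247 UMIs per 10000 UMIs, and the lowest point below the highest mode lay at 37.0, all taken from the cells of both hashed samples together. Neither hashed sample alone had a clear dip at that level: hashed sample 2 had its lowest bin between the peaks somewhat above it, with 28 cells from 1.7 to 1.8 on the log10 scale, and hashed sample 1 had no clear dip. Below it were 18.5% of resident macrophage-like cells in hashed sample 1 (16.1 to 21.1, 176 of 951 cells) and 42.2% in hashed sample 2 (39.6 to 44.8, 590 of 1399 cells). The median level was 8.88 in the MHC II-low cells and 207 in the MHC II-high cells, a 23.3-fold difference, with medians of 6517 and 5447 UMIs per cell. The 3 genes lie close together on chromosome 17 (GRCm38): H2-Ab1 at 34257689 to 34269419, H2-Aa at 34282744 to 34287823 and H2-Eb1 at 34305867 to 34316674.

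The level in MHC II-low macrophages was nearer that of T cells, which do not make these proteins, than that of MHC II-high macrophages. CD4 T cell-like cells, in which UMIs of these genes can come from free RNA, had median levels of 5.81 and 7.07 per 10000 UMIs. The mixed T cell-like cluster, deeper at a median of 10436.5 UMIs per cell, had only 2.67 and 2.63. NK cell-like cells, with a median of 3250 UMIs, had 9.15 and 8.6. The background level thus differed between classes of different depth, so that no single value marks absence of these genes. H2-Aa stood at 524 and 374 CPM in MHC II-low cells, against 279 and 240.3 CPM in CD4 T cell-like cells, 8587 and 7539 CPM in MHC II-high cells, and 12848 and 11789 CPM in type 2 dendritic cell-like cells. Cd74, the invariant chain of MHC class II, remained higher in MHC II-low macrophages (2147 and 1784 CPM) than in CD4 T cell-like cells (635 and 622 CPM), while MHC II-high macrophages had 20856 and 20266 CPM. Ciita, the master activator of these genes, was at 13.4 and 9.22 CPM in MHC II-low and 81.8 and 118 CPM in MHC II-high cells. The states are ranges of a continuous level, and 224 of 2350 cells (9.53%) lay within 1.5-fold of the dividing level.

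The MHC II-low share differed between the resident macrophage-like clusters. It was highest in cluster 7, led by Ccl8, F13a1 and Cd163, at 51.5% and 74.3%, and next in cluster 1, led by Ccl12, Ccl7 and Pf4, at 30.4% and 55.5%. In cluster 3, led by the chemokines Ccl3 and Ccl4 and the stress gene Hspa1a, it was 12.1% and 21.5%. Cluster 4, led by Apoe and Fcgr4, had 3.92% and 17.0%, and cluster 10, of shallow cells with a median of 1459 UMIs, 11.4% and 33.6%. The share was thus higher in hashed sample 2 in each of the 5 clusters. Cluster 1 held 14.2% of resident macrophage-like cells in hashed sample 1 and 38.1% in hashed sample 2, and cluster 4 held 34.9% and 14.3%. Monocyte-like cells were below the dividing level in 54.8% and 55.6%. Cluster 7 had the monocyte marker F13a1 and no marker of its own class among its 10 leading genes, and without it the MHC II-low share was 11.7% and 37.2%.

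**Figure D2:**
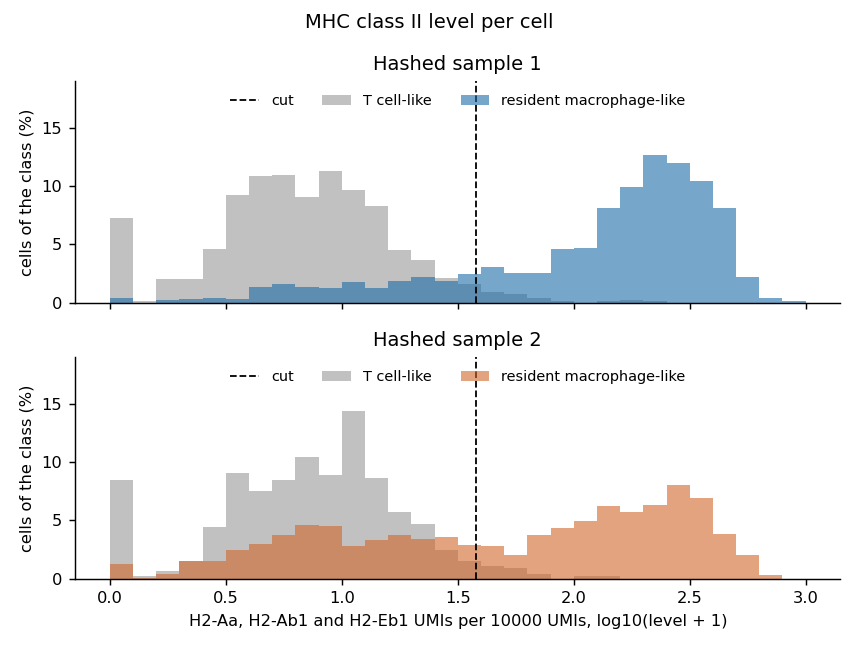
Distribution of the summed UMIs of H2-Aa, H2-Ab1 and H2-Eb1 per 10000 UMIs, as log10(level + 1) on the horizontal axis, with the share of the cells of the class (%) on the vertical axis. Coloured bars are resident macrophage-like cells, grey bars T cell-like cells and the dashed line the dividing level of 37.0, below which lay 18.5% of the macrophages in hashed sample 1 and 42.2% in hashed sample 2.

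The measured genes of long-lived tissue macrophages were higher in MHC II-low than in MHC II-high resident macrophages. All 5 measured members of that list of 10 were counted as higher, with a median log2 ratio of 1.49 and 1.37, above all 10000 random lists. Lyve1 and Cbr2 reached the 50 CPM needed to be measured in MHC II-low cells alone. Among the members not measured, Timd4 had 0 CPM in every resident macrophage-like cluster, and Cd209f and Cd209g had at most 2.56 CPM. Within single clusters the medians over the members measured there were smaller, at 0.36 and 0.42 in cluster 1 (4 genes), 0.67 and 0.51 in cluster 3 (2 genes) and 0.54 and 0.42 in cluster 7 (7 genes). The 5 genes were the hyaluronan receptor Lyve1 (93.7 and 51.0 CPM against 4.48 and 3.74), the mannose receptor Mrc1 (1758 and 1657 against 846 and 893), the scavenger receptor Stab1 (963 and 954 against 450.0 and 481), Gas6, a ligand of the engulfment receptors Axl and Mertk (264 and 279 against 87.7 and 102), and Cbr2. Lyve1 was 20.9-fold (12.8 to 36.1) and 13.6-fold (8.29 to 23.8) higher. Il1b, encoding interleukin 1 beta, was lower, at 72.3 and 60.9 CPM in MHC II-low and 201 and 243 CPM in MHC II-high cells, but it was carried mainly by cluster 3 (705 and 479 CPM) and within none of clusters 1, 3 and 7 did it pass 1.5-fold in both hashed samples. Over all 2698 measured genes, 54 were counted as higher and 30 as lower, and the lower ones included all 7 measured MHC class II genes. Across genes, the log2 ratios of the hashed samples correlated with Pearson r of 0.839. That value includes the 3 genes that made the split. Spearman rho was 0.617, and 77.2% of genes had the same sign in both hashed samples.

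The 10 genes furthest above were Lyve1, Ltc4s, Cbr2, F13a1, Fcrls, Ccl8, Stard8, Gas6, Igf1 and Pmp22. Ltc4s, the synthase of leukotriene C4, had log2 ratios of 1.90 and 1.77, F13a1, a subunit of coagulation factor XIII, 1.68 and 1.79, the chemokine Ccl8 2.19 and 1.06, and the growth factor Igf1 1.68 and 1.15. The 10 furthest below were Plbd1, Il1b, Mgl2, Napsa, Hspa1a, Ccr2, Rgs1, Hspa1b, Socs3 and Plxdc2. The lectin Mgl2 had log2 ratios of -1.36 and -1.42, and Ccr2, the receptor that guides monocytes out of the blood, -1.63 and -0.91.

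Among the other lists, identity genes of resident macrophages were alike in both states, but this list overlaps the markers that named the cells. Their likeness is therefore in part set by the naming. Of 12 measured complement and identity genes 11 were neither higher nor lower, among them C1qa (8120.5 and 7162.5 CPM in MHC II-low against 7141.5 and 6801 in MHC II-high), and the transcription factor Maf was higher (log2 0.96 and 0.84). MHC class I genes did not separate the states, with 0 of 7 counted and B2m at 2056 and 1518 against 1995 and 1577 CPM, nor did lipid-associated macrophage genes (0 of 7), costimulation genes (0 of 3) or tubular RNA (0 of 3). Of 11 lysosome genes the cathepsins Ctsb, Ctsd and Ctsl were higher and none lower, with Ctsd at log2 1.12 and 1.07. Of 8 inflammatory genes the monocyte-attracting chemokines Ccl2 (log2 0.89 and 0.67) and Ccl7 were higher, and Il1b, Ccl3 and Ccl4 lower. Igf1 and Ccl8 were higher among 5 repair and fibrosis genes, and the heme-degrading enzyme Hmox1 (log2 0.98 and 1.26) among 6 hypoxia and glycolysis genes. Of 6 monocyte-derived genes F13a1 was higher and Ccr2 lower. All 7 measured MHC class II genes were lower, H2-Aa, H2-Ab1 and H2-Eb1 by construction and Cd74, Ciita, H2-DMa (log2 -1.20 and -1.38) and H2-DMb1 (-2.30 and -2.33) without having entered the split. No cell cycle gene was measured.

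Dissociation stress genes, induced during tissue digestion, moved with the states: 7 of 11 were lower in MHC II-low cells, including Fos (log2 -0.85 and -0.71), Atf3, Dusp1 and Hspa1a, and none was higher. The median of that list, -0.74 and -0.76, lay below all 10000 random lists, and was nearer 0 within clusters 1 (-0.47 and -0.16), 3 (0.01 and -0.43) and 7 (-0.35 and -0.48). Per cell, the median sum of those genes was 8.50 and 11.8 UMIs per 10000 in MHC II-low and 17.6 and 19.9 in MHC II-high cells. Summed per marker set, markers of other cell types were low in both states as medians over cells. Classical monocyte markers summed to 8.42 and 10.2 UMIs per 10000 in MHC II-low and 7.54 and 9.69 in MHC II-high cells, against 60.0 and 55.0 in monocyte-like cells. These near-equal sums hide opposite moves within the set. F13a1 stood at 731 and 490 CPM in MHC II-low against 222 and 134.5 CPM in MHC II-high cells. Ccr2 stood at 153.5 and 377 CPM against 495 and 719 CPM, with 779 and 1331 CPM in monocyte-like cells. Type 2 dendritic cell markers summed to 0 and 1.04 in MHC II-low against 1.53 and 3.43 in MHC II-high cells, with 29.4 and 38.9 in type 2 dendritic cell-like cells.

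The Lyve1 and Ccl8 difference belonged largely to 1 cluster. Clusters 1 and 7 held 44.0% and 29.1% of the MHC II-low cells but 20.9% and 8.02% of the MHC II-high cells, and cluster 7 had Ccl8 at 2674 and 1850.0 CPM and Lyve1 at 97.5 and 138 CPM, against 254 and 257 CPM and 12.8 and 8.06 CPM in cluster 1. Within cluster 7, MHC II-low cells were higher in Lyve1 (mean log2 3.66) but not in Ccl8 (0.64 and -0.64). Within cluster 1 neither was higher (mean log2 -0.35 for Lyve1 and -0.16 for Ccl8), and 14 genes were counted as higher and 10 as lower, whereas in cluster 3 these numbers were 49 and 15. Cluster 3 had fewer MHC II-low cells, 25 and 71, than cluster 1, with 41 and 296, so that counting error weighs more on its numbers. Mrc1 and Stab1 were above 0 within clusters 1, 3 and 7 without passing 1.5-fold in both hashed samples, except Stab1 in cluster 3 (log2 1.11 and 0.77). Plbd1 was lower within clusters 1, 3 and 7 (mean log2 -1.62, -1.05 and -1.27).

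No replicate check stands behind these counts. For scale, 77 genes within MHC II-low cells and 60 within MHC II-high cells differed by at least 1.5-fold between the hashed samples. With TMM factors in place of total UMIs, the median over all genes moved from 0.12 to -0.01 and the counts from 54 higher and 30 lower (64.3% higher) to 37 and 43 (46.2% higher). Relative to that shift Ctsb and Ccl2 no longer passed the rule, Lyve1 fell under the level needed to be measured, and Jun, Fosb and Nfkbiz were counted as lower, with no named gene turning direction.

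**Figure D3:**
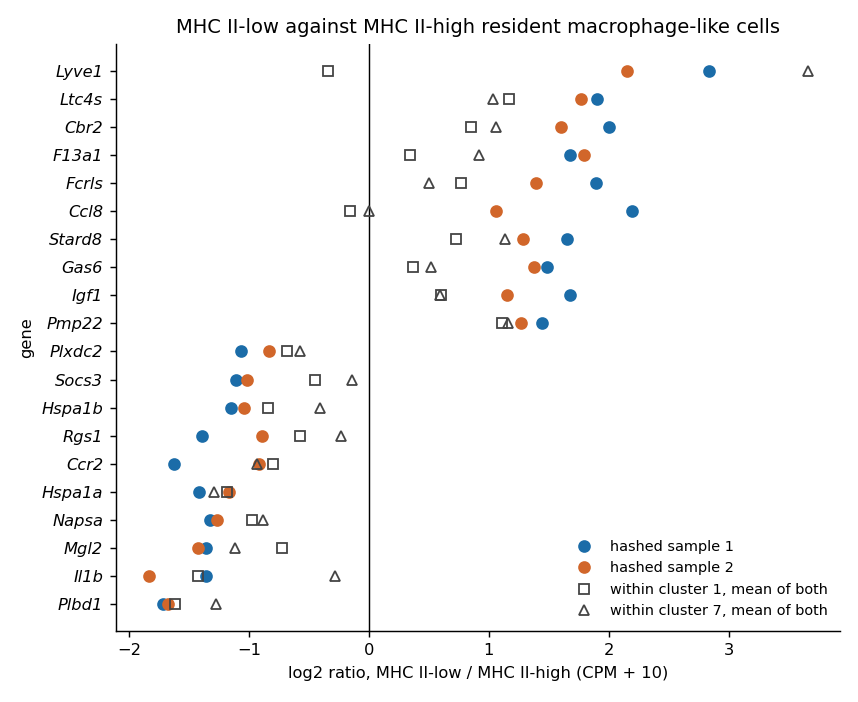
Log2 ratio of CPM + 10 in MHC II-low over MHC II-high resident macrophage-like cells (horizontal axis) for the 10 genes furthest above and the 10 furthest below (vertical axis). Filled points are the hashed samples and open symbols the means of both within single clusters, where Lyve1 lies at -0.35 in cluster 1 and 3.66 in cluster 7.

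Resident macrophages were next set against monocyte-like cells, the blood-derived cells of the same sort. Higher in the resident macrophage-like cells were Ccl8, by 55.7-fold (29.3 to 121.9) and 23.5-fold (13.98 to 43.0) and mainly from cluster 7, since cluster 3 was near the monocyte level with 19.3 and 14.03 CPM, Pf4, by 26.3-fold and 17.6-fold, and Mrc1, by 8.12-fold and 9.63-fold. C1qa, a subunit of the complement starter C1q, stood at 7346 and 6968 CPM against 767 and 557 CPM. Monocyte-like cells were higher in the matrix glycoprotein Thbs1 (484 and 498 CPM against 6.16 and 7.22) and in Il1b (1285 and 2388 CPM against 174 and 159). Of 2851 measured genes, 250 were counted as higher and 248 as lower in resident macrophages, and the log2 ratios of the hashed samples correlated with Pearson r of 0.915 across genes.

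The 10 genes furthest above were Ccl8, Pf4, Ccl12, Cd63, Pmepa1, Stab1, Gas6, Col14a1, Fcrls and Mrc1, and the 10 furthest below were Thbs1, Ifitm6, Hp, Gsr, Il1b, Gpr141, Ear2, Klf2, Adgre5 and Itgal. Of 12 complement and identity genes 11 were higher, among them C1qa, Cd81 and Mertk, and of 9 measured monocyte-derived genes 6 were lower (Chil3, Plac8, S100a4, Vcan, Fn1 and Ccr2) while F13a1 was higher (328 and 299 CPM against 95.8 and 124.5). Both lists overlap the markers that named the cells. Among 12 lysosome genes 7 were higher, including Ctsb (log2 1.34 and 1.64) and Grn, and the fatty acid receptor Cd36 was lower (-2.29 and -2.16). All 3 measured long-lived tissue macrophage genes (Mrc1, Gas6 and Stab1) were higher. Of 10 inflammatory genes Ccl2, Ccl7 (log2 3.02 and 3.03) and Cxcl16 were higher and Il1b lower, and of 6 repair genes Igf1 and Ccl8 were higher and Tgfb1 and Tgm2 lower. Of 9 lipid-associated genes Trem2, Spp1, Apoe and Cd63 were higher and Fabp5 and Lgals3 lower. Of 6 hypoxia and glycolysis genes Hif1a, Pkm and Eno1 were lower (Hif1a log2 -0.95 and -0.94). MHC class II genes (0 of 7) and MHC class I genes (0 of 7) were not counted either way.

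Dissociation stress genes were lower in resident macrophages than in monocyte-like cells, at 9 of 11, with Fos at 540 and 472 CPM against 1761 and 1979 CPM, and their median per cell in monocyte-like cells was 48.2 and 55.2 UMIs per 10000. The monocyte-like cluster, of 135 and 162 cells, joined classical (Chil3, Plac8) and patrolling (Ace, Treml4, Adgre4) markers, so that its values are a mixture. Because clusters were formed on expression, genes that separate these classes are in part what defined them.

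**Figure D4:**
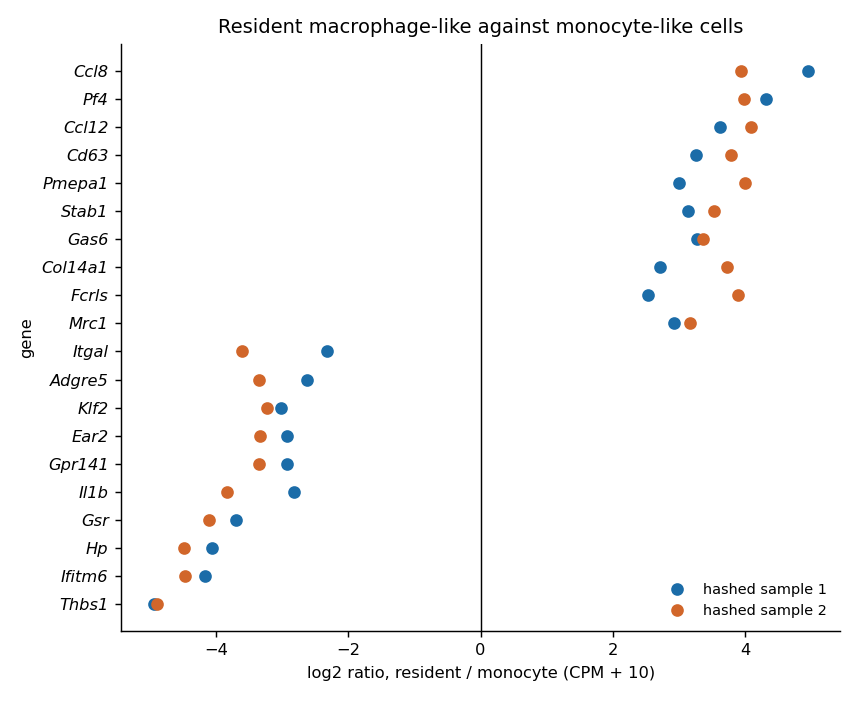
Log2 ratio of CPM + 10 in resident macrophage-like over monocyte-like cells (horizontal axis) for the 10 genes furthest above and the 10 furthest below (vertical axis). Points are the 2 hashed samples, and Ccl8 lies at 4.95 and 3.94 and Thbs1 at -4.93 and -4.88.

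CD4 T cells, the other population of the design, included cells with the regulatory gene Foxp3. Of T cell-like cells, 32.5% (29.5 to 35.6) and 27.3% (23.2 to 31.6) had a Cd4 UMI and none of Cd8a or Cd8b1, 30.4% and 38.1% had a Cd8a or Cd8b1 UMI and none of Cd4, and 35.2% and 33.5% had neither. A cluster led by Ikzf2, Foxp3 and Ctla4 held 14.01% (11.3 to 17.1) and 8.98% (5.78 to 13.2) of CD4 T cell-like cells. With cells thinned to 1000 UMIs, Foxp3, the defining transcription factor of regulatory T cells, was detected in 4.98% (2.82 to 8.09, 15 cells) and 4.13% (1.36 to 9.38, 5 of 121 cells) of the cells with a Cd4 UMI, and in 0 of 263 and 0 of 161 CD8 T cell-like cells. These zeros allow up to 1.14% and 1.86% of cells with a UMI at that depth and set no limit on cells expressing it. Without thinning, the Foxp3 shares were 10.8% and 10.6%, at median depths of 4879 and 3666 UMIs, against 0.210% and 0.214% of resident macrophage-like cells with 5485 and 6001 UMIs.

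Other genes were detected in larger shares of the CD4 cells. After thinning, the costimulatory receptor Tnfrsf4 (OX40) was detected in 28.9% and 33.1% of them and in 3.04% and 1.24% of CD8 T cell-like cells, whose median depth was 3189.5 and 3288 UMIs. The survival receptor Il7r was detected in 42.5% and 38.8%, against 28.5% and 24.8% in CD8 T cell-like and 0.437% and 0.814% in resident macrophage-like cells, and the chemokine receptor Cxcr3 in 18.3% and 19.01%, against 13.7% and 22.4% in CD8 T cell-like and 0.983% and 0.888% in resident macrophage-like cells. Gata3 was detected in 11.96% and 14.05% and Ifng, encoding interferon gamma, in 7.31% and 4.13%, with 13.7% and 10.6% for Ifng in CD8 T cell-like cells. In resident macrophage-like cells Ifng was detected in 0 cells, which allows up to 0.328% and 0.222% of cells with a UMI at that depth, and Gata3 in 0% and 0.148%. The unthinned shares were 68.2% and 56.1% for Tnfrsf4, 78.4% and 72.4% for Il7r, 59.3% and 49.6% for Cxcr3, 36.4% and 35.0% for Gata3, and 26.6% and 18.7% for Ifng, and among these genes the highest share in resident macrophage-like cells was 3.68%, for Cxcr3 in hashed sample 1. Il17a was detected in 1 cell of hashed sample 1 and none of hashed sample 2, and Il4 in 0 cells of either, which for Il4 allows up to 0.997% and 2.48% of cells with a UMI at that depth and sets no limit on cells expressing it.

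Against CD8 T cell-like cells, CD4 T cell-like cells were higher in the 4 measured genes of the regulatory T cell list, Foxp3 not among them. They were lower in 5 of 6 cytotoxicity genes. The chemokine Ccl1 stood at 351 and 597 CPM against 3.18 and 9.13 CPM, with 3 and 5 UMIs in CD8 T cell-like cells, a 110.3-fold (37.6 to 535.9) and 65.4-fold (27.9 to 202) difference, and Tnfrsf4 at 504 and 452 CPM against 25.4 and 9.13 CPM. The cytotoxic chemokine Ccl5 was 3.73-fold (3.60 to 3.87) and 4.87-fold (4.60 to 5.16) higher in CD8 T cell-like cells, and the granule protein gene Nkg7 3.77-fold and 4.06-fold. Of 2767 measured genes, 126 were counted as higher and 83 as lower in CD4 T cell-like cells, and the log2 ratios of the hashed samples correlated with Pearson r of 0.797 across genes.

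The 10 genes furthest above were Ccl1, Tnfrsf4, Izumo1r, Tnfsf8, Tbc1d4, Tnfsf11, Ikzf2, Odc1, Tspan32 and Fabp5, and the 10 furthest below were Klrk1, Ly6c2, Klrd1, Cd7, Gzmb, Gzmk, Ccl5, Nkg7, Cd160 and Atp8b4. All 4 measured regulatory T cell genes were higher (Ikzf2, Ctla4, Tnfrsf18 and Tnfrsf4, median log2 1.82 and 1.90). Foxp3, Il2ra and Il10 of that list were not measured. Tnfrsf4 also led cluster 0, the larger CD4 T cell-like cluster of 724 cells, so that it did not mark the Foxp3-led cluster alone. All 6 measured cell cycle genes were higher too, such as Mki67 (80.85 and 72.0 CPM against 33.9 and 27.4), although the cycling mixed cluster was left out of both classes. Of 5 hypoxia and glycolysis genes 4 were higher (Hif1a, Ldha, Pgk1 and Pkm, with Hif1a at log2 1.09 and 1.26). Of 6 cytotoxicity genes 5 were lower (Gzmb, Gzmk, Nkg7, Ccl5 and Fasl, median log2 -1.79 and -2.13), and of 4 tissue residency genes Cxcr6 and Itga1 were lower. Gata3 was the measured gene of the Th2 list and was higher (log2 0.74 and 1.28), while of 4 Th1 genes only Cxcr6 was counted, as lower. The naive (0 of 4), follicular helper (0 of 2), MHC class I (0 of 10) and dissociation stress (0 of 9) lists held no counted gene, and no Th17 gene was measured.

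These are values of 571 and 256 CD4 T cell-like and 266 and 170 CD8 T cell-like cells, and the regulatory list rests in part on the Foxp3-led cluster. Clustered alone, the cells of hashed sample 2 gave no separate CD4 or CD8 cluster, and 13.5% of its cells fell in mixed T cell clusters.

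**Figure D5:**
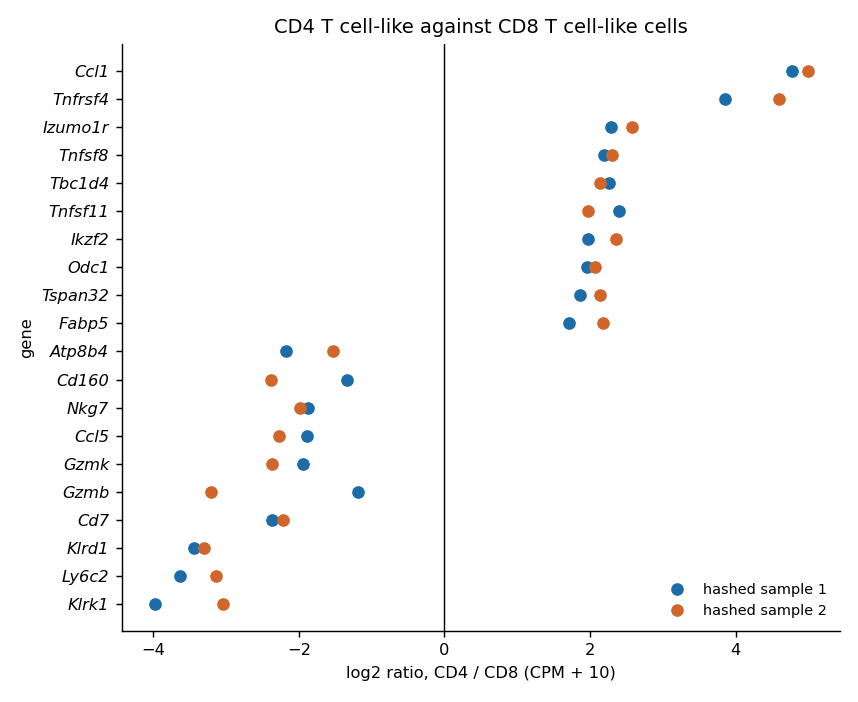
Log2 ratio of CPM + 10 in CD4 T cell-like over CD8 T cell-like cells (horizontal axis) for the 10 genes furthest above and the 10 furthest below (vertical axis). Points are the 2 hashed samples, with Ccl1 at 4.77 and 4.99 and Klrk1 at -3.98 and -3.04.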

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

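Of the tests below, the 3 on dendritic cell RNA, free MHC class II RNA and dilution by macrophages were chosen after the result was seen. A hashtag that the run settings assign to no sample stood out because it was used in no comparison: it had 286 UMIs in 273 of the 7015 deposited cells, of which 263 cells were in hashed sample 1 and 10 in hashed sample 2, with at most 2 UMIs in a cell.

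The first pattern was that resident macrophage-like cells held MHC II-low and MHC II-high cells, parted at a level where neither hashed sample alone had a clear dip. If recently arrived monocytes made up the low state, monocyte markers should reach at least 50% of their level in monocyte-like cells. The median over 12 such markers was 4.75% (3.61% in hashed sample 2), but MHC II-high cells had 5.80% and 4.83% and the cells had been named with these markers, so that the test decides nothing and that explanation stays open. RNA or doublets of type 2 dendritic cells would need to supply 61.7% and 59.6% of the UMIs of MHC II-high cells and so dilute C1q, but C1qa, C1qb and C1qc together stood at 0.885 and 0.957 of their level in MHC II-low cells. These genes also helped to name the clusters, so that cells with much dendritic cell RNA could have been left out of the class. The ratio therefore speaks only for the cells kept in it. Stress from digestion moved with the states, yet in the 784 cells with the fewest stress UMIs the long-lived tissue macrophage genes still had a median log2 ratio of 1.59 and 1.24, so that stress is not the whole source of that difference.

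The second pattern was the higher MHC II-low share in hashed sample 2. Thinning every cell to 1000 UMIs left shares of 17.7% and 41.2%, a ratio of 2.33, which argues against depth. Among the cells with the fewest stress UMIs the shares were 28.8% and 54.7%, a ratio of 1.90, against stress as the whole cause. The median level in T cell-like cells, a measure of free MHC class II RNA, was 1.17 times as high in hashed sample 2 (6.75 against 5.75 per 10000), but droplets of 1 capture share their free RNA, so that this ratio decides nothing. The sample title names weeks 1 and 2 while the run settings name week 2 for both hashed samples: a difference in time stays open, untested, as do differences in digestion before pooling.

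The third pattern was the lower T cell-like share in hashed sample 2. Weaker hashtag labelling was not seen among the T cells kept: their median own hashtag count over that of resident macrophages was 1.57 times as high in hashed sample 2 as in hashed sample 1 (2841 over 783 against 2315 over 1002). The matrices hold only barcodes already assigned to a hashtag. T cells lost through weak labelling would be missing from them, so this ratio cannot show such a loss. Dilution by resident macrophage-like cells alone would leave the T cell share of the remaining cells alike, but it was 44.0% in hashed sample 1 and 21.9% in hashed sample 2, a ratio of 0.497. Other myeloid cells stayed among the remaining cells in that test. All named myeloid classes together made up 46.8% and 61.5% of cells, and the unnamed clusters 16.4% and 19.6%. Dilution by myeloid cells as a whole therefore stays open. The sort and digestion of each hashed sample remain open, and so does the difference in time that the title leaves possible, which was not tested.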

How the results depend on the processing

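The alternatives that left out cluster 7 or the shallow cluster, looked within single clusters or took the cells with the fewest stress UMIs were chosen after the data were seen; the others were fixed before. Of 1195 alternative values, 909 stayed within the main interval or within 1.5 times the main count, 280 moved and 6 reversed. Of the 920 for named genes, 183 moved and the 6 reversals were of genes called higher in MHC II-low cells: mean log2 of Lyve1 was -0.35 within cluster 1 and -0.0480 within cluster 3, of Ccl8 -0.16 and -0.998, and within cluster 3 of Ltc4s -0.32 and of Cbr2 -0.0280. All but Ccl8 within cluster 1 were under the level needed to be measured there, and no cause was tested.

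Shares here are means of both hashed samples. The resident macrophage-like share of 35.6% was 40.3% at resolution 0.5 and 38.8% at resolution 2. Clustered alone, hashed sample 1 had 28.3%, against 30.85% in the joint clustering, and hashed sample 2 had 30.1%, against 40.41%. The size of the difference between the hashed samples thus depended on the clustering. The CD4 T cell-like share of 12.96% was 9.38% at resolution 2 and between 0 and 17.0% with hashed samples alone, and the CD8 T cell-like share of 6.77% was 8.19% with the strict cell filter, 8.37% at resolution 0.5 and 0 to 10.4% with hashed samples alone. The zeros come from hashed sample 2, whose T cells then fell in mixed clusters. The monocyte-like share of 4.53% was 6.12% without hashed sample 1 and 4.45% without hashed sample 2. The MHC II-low share of 30.3% was 22.1% at 0.5 times and 38.3% at 2 times the dividing level, 19.6% to 49.95% with hashed samples alone, 24.4% without cluster 7 and 41.7% among the cells with the fewest stress UMIs, and with both hashed samples in use it was 1.90 to 3.19 times as high in hashed sample 2 under every setting. The Foxp3 share was 10.7% without thinning and 4.56% with it.

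Counts of genes moved with the strictness of the rule. In MHC II-low cells the 54 higher genes became 32 with a pseudocount of 50 CPM, 23 at 200 CPM, 12 at 2-fold, 119 between the cells of lowest and highest level, 33 without cluster 7, 14 within cluster 1, 30 within cluster 7 and 58 to 143 with hashed samples alone; the 30 lower genes became 50 with the strict cell filter, 50 with no filter on low values, 18 at 200 CPM, 14 at 2-fold, 10 within cluster 1, 15 within cluster 3 and 38 to 49 with hashed samples alone. Against monocytes, the 250 higher and 248 lower genes became 574 and 435 with no filter on low values, 73 and 102 at 200 CPM, 131 and 127 at 2-fold, and 369 to 389 and 369 to 390 with hashed samples alone. In CD4 T cells, the 126 higher and 83 lower genes became 53 and 42 with a pseudocount of 50 CPM, 316 and 157 with no filter on low values, 26 and 25 at 200 CPM, 35 and 30 at 2-fold, and 252 to 352 and 161 to 167 with hashed samples alone. A rule asked of 1 hashed sample is looser by construction. The hashtag rule passed 3315 and 3694 cells at minimums of 5, 10 and 20 counts.

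No test blocked on the hashed sample was made, by choice: the plan made it depend on named animals, and the labels do not say which animals the hashed samples are. The blocked fit, the fit without a block and the DESeq2 fit were therefore left out. Small classes were less alike between the hashed samples: 60.3% of genes in B cell-like and 31.1% in NK cell-like cells lay 1.5-fold apart, against 3.44% in resident macrophage-like cells. Depth, cell number and real differences were not separated.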

Other observations

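The clusters and genes described here were chosen only after the data were seen. Among the myeloid clusters that stayed unnamed, cluster 8 (5.74% and 3.73% of cells) had the arginine-degrading enzyme Arg1 at 751 and 543 CPM against 28.7 and 12.8 CPM in resident macrophage-like cells, the elastase Mmp12 at 2724.5 and 1972.5 CPM against 26.9 and 57.7, the lipase Lpl at 1475.5 and 1106 CPM against 45.5 and 118, and Spp1, encoding osteopontin, at 1168 and 1762 CPM against 193 and 330.5. Unnamed cluster 2 shared part of this, with Mmp12 at 944 and 1039.8 CPM and Lpl at 399 and 455 CPM. Cluster 8 also had Fn1, encoding fibronectin, at 2004 and 1691 CPM, Gpnmb at 78.7 and 131 CPM and Timp1 at 224 and 209 CPM, with C1qa at 2315 and 2732 CPM. Cluster 14 (2.59% and 1.62% of cells) carried interferon response genes, with the T cell-attracting chemokines Cxcl9 at 3295 and 2139 CPM and Cxcl10 at 1111 and 1823.5 CPM, against 51.7 and 23.8 and 29.5 and 30.4 CPM in resident macrophage-like cells, and with C1qa at 4475 and 4655 CPM.

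Cluster 2 (6.68% and 10.5% of cells) joined Ear2 (892 and 789 CPM), Mgl2 (1229 and 2025 CPM), Ccr2 (1176 and 1476 CPM) and H2-Aa (10035 and 9548 CPM) with C1qa at 2755 and 3299 CPM, between the resident macrophage-like cells (7346 and 6968 CPM) and the type 2 dendritic cell-like cluster 5 (192.5 and 202 CPM). Cluster 12 (1.39% and 3.73%) was of cycling cells, with Mki67 at 750.5 and 970.1 CPM, and held C1qa at 2647 and 4204 CPM; its Arg1 level was 938.5 CPM in hashed sample 1 and 40.7 CPM in hashed sample 2. In cluster 20, loop of Henle or distal tubule-like, with Umod at 1911 and 1172 CPM, Lcn2 stood at 1716.5 and 1889 CPM and Spp1 at 14593 and 20801 CPM, whereas the proximal tubule-like cluster 13 had Lcn2 at 4.88 and 13.1 CPM and Spp1 at 1813 and 1087 CPM. Ptprc, which encodes CD45, was at 200 and 206.5 CPM in cluster 20, against 304 and 354 CPM in resident macrophage-like cells, and C1qa was at 1117 and 1587.5 CPM.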
